A study of Mus musculus with 12 samples.

How the data were processed

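RNA levels were measured on 12 one-colour Affymetrix arrays hybridised with biotinylated cRNA from mouse splenic B cells. The cells were sorted by flow cytometry on B220, a surface protein carried by most B cells. The mice had a mixed strain background, per the labels. Per the labels, the deleted genotype was Foxp1flox/del and the control genotype Foxp1wt/flox, where flox is a conditional allele and del a deleted one. All cells were incubated for 4 h, with or without addition of what the labels call IgM. The labels do not say whether or how the conditional allele was recombined, nor whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples.

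The deposited log2 values were made with GCRMA, per the submitters' processing notes. GCRMA corrects background from probe sequence, normalizes arrays by quantiles and summarises probes into probe sets. Its version and settings were not given in the sources used here. The log2 scale was read from the values themselves: the highest was 15.79, or 56572 on the linear scale, and all arrays shared a floor of 2.23. The values were not centred per gene. Values close to the floor have no order among themselves, so a change from such a level is compressed. Per array, 58.9% to 59.9% of probe sets lay at or below 4. Array data carry no read depth, and the number of arrays limits the precision.

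The array held 45101 probe sets, of which 64 were controls. The platform annotation named 1 gene for 34945 of the others, several genes for 932 and none for 9160. Symbols were updated through gene identifiers for 34741 probe sets, with a gene table of assembly GRCm38.p6. That table also gave each gene's chromosome and genomic span. Probe sets with several genes or none were left out. A probe set was kept when its log2 value was above 4 on at least 3 arrays, and 19187 passed, with or without a gene name. Each gene was represented by the passing probe set with the highest mean over the 12 arrays, which gave 9293 genes. Genes without such a probe set were not analysed here.

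Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on the deposited log2 values. One mean was fitted for each of the 4 groups, with 1 shared estimate of the spread per gene. Replicate numbers did not enter this fit, so differences between them remained in the spread. The 5 comparisons were deleted against control without IgM, deleted against control with IgM, IgM against no IgM in each genotype, and the interaction, which is the genotype difference with IgM minus that without. Tests were two-sided, with Benjamini-Hochberg adjustment over the 9293 genes and a threshold of 0.05. Errors of fold changes are standard errors from this model. Genes named in the text were set by a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and the 10 largest falls past the threshold in which all 3 samples of one group lay beyond all 3 of the other. That last condition was not applied to the interaction. Predicted genes and clones were skipped. Foxp1, Bcl2l1, Bcl2, Mcl1 and Bcl2l11 were always included, and each described list gave up to 4 of its most changed members past the threshold, or up to 2 with the smallest p where none passed. The 35 gene lists, and the alternatives and tests other than those named here or in the closing section as chosen later, were also fixed then.

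Of the 35 lists, 33 had at least 5 measured members and were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison. The platelet and stromal lists had 2 and 1 measured members and were not tested. Each test was repeated with a correlation estimated for the list, and with fry, which asks whether a list's genes move on balance in one direction.

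Replicate numbers 1 to 3 came from the labels and recur in every group, and the array names in the labels differ in form between the numbers. Deviations of same-numbered arrays from their group means were correlated across genes. The correlations were 0.55 to 0.78 between genotypes without IgM, 0.17 to 0.80 between genotypes with IgM, 0.69 to 0.85 in control cells and 0.32 to 0.72 in deleted cells. All exceeded 0.1, so the numbers were taken to pair the samples, and values from a fit with the replicate number as a block are given where they change the call of a list or of a named gene, or move a count of genes by more than 1.5 times. Differences in array quality were tested over all regroupings of the 12 arrays and, chosen after the data were seen, by an exact sign-flip test within same-numbered pairs.

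Other alternatives covered the filter, normalization, choice of probe set, variance model, array weights, threshold, and leaving out arrays. Weights were estimated gene by gene, because the default algorithm of arrayWeights did not converge on these data. That choice was made after the failed fit was seen.

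The model was tested on simulated data with the means, replicate deviations and residual spread of the 9293 genes, in which 50 genes for each size of change were altered between deleted and control cells without IgM. Without the block, 20% of genes with a true log2 change of 1 were recovered, 54% of those with 2, 86% with 3 and 98% with 4, beside 1 false call. With the block the shares were 50%, 84%, 100% and 100%, beside 10 false calls. The altered genes all had mean log2 values above 6, and all arrays had the same residual spread for a gene. These shares therefore do not apply to genes near the floor or to an array with a larger spread. In a simulation of the same comparison over 9293 genes, camera called 5 of 5 lists shifted by 1 log2 unit and 0 of 20 unchanged lists. Residual noise was drawn independently for each gene and the lists were random genes. The preset correlation was therefore not tested on lists whose members vary together.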

Results

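The 12 arrays covered splenic B220-positive B cells of 2 Foxp1 genotypes, each without stimulation and after 4 h with IgM, with 3 arrays in each of the 4 groups. Foxp1 encodes a forkhead transcription factor of lymphocytes. Median log2 values of replicates 1, 2 and 3 were 2.47, 2.45 and 2.49 in deleted cells with IgM and 2.49, 2.47 and 2.47 in deleted cells without it. They were 2.48, 2.45 and 2.46 in control cells with IgM and 2.48, 2.46 and 2.48 in control cells without it. Across the tested genes, arrays of one group correlated at 0.951 or more, except where deleted IgM replicate 3 was involved, which correlated at 0.817 with a group mate. That array also had the lowest level of the bacterial poly-A control RNAs, 6.94 against 8.05 to 10.73 on the other 11 arrays. Its values relative to the other arrays of its group fell with shorter genomic span, with a median log2 difference of -1.29 in the class with the shortest genes and 0.81 in that with the longest, of 5 classes equal in number. The mean poly-A control level differed by -0.26 between deleted and control arrays (exact two-sided permutation test, p = 0.688, adjusted p = 0.911 over 8 tests of array quality) and by -0.65 between IgM and unstimulated arrays (exact two-sided permutation test, p = 0.327, adjusted p = 0.911). Within same-numbered pairs it was lower with IgM in 6 of 6 (exact two-sided sign-flip permutation test, p = 0.0312, the smallest that 6 pairs allow, adjusted p = 0.25 over 8 tests). Xist, which is transcribed in female cells, lay at 2.23 to 2.44 on the 4 arrays of replicate 1. It lay at 7.67 on deleted IgM replicate 3 and at 10.75 to 11.75 on the other arrays of replicates 2 and 3. The Y-linked gene Eif2s3y lay at 7.97 to 10.66 on all 12 arrays.

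**Figure D1:**
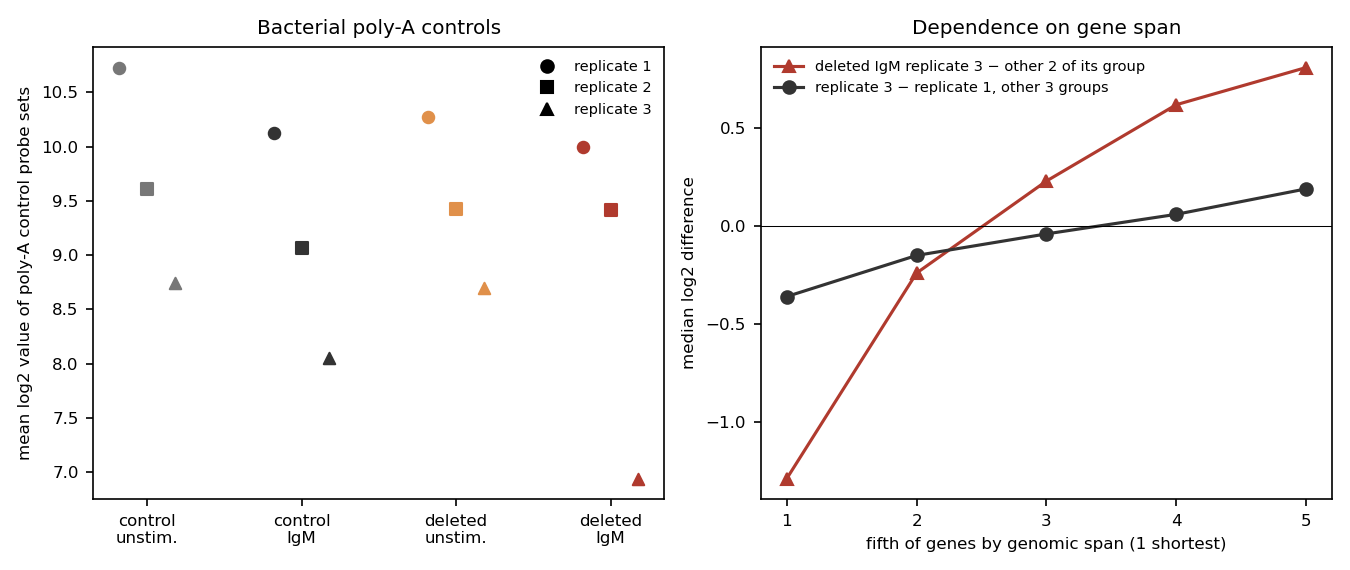
Mean log2 value of the bacterial poly-A control probe sets on each of the 12 arrays, by group, with symbols for the replicate number (left), and median log2 difference between arrays over 5 equal classes of genes by genomic span (right), for deleted IgM replicate 3 against the other arrays of its group and for replicate 3 against replicate 1 in the other 3 groups. Deleted IgM replicate 3 has the lowest control level, 6.94, and its median difference runs from -1.29 in the shortest genes to 0.81 in the longest.

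Foxp1 itself was read by 8 probe sets, and no probe set differed between genotypes past the threshold. The probe set with the highest signal had a mean log2 value of 12.90 ± 0.55 (SD, n = 3) in unstimulated control cells and 12.87 ± 0.53 (SD, n = 3) in unstimulated deleted cells. With IgM the means were 12.68 ± 0.53 (SD, n = 3) and 12.65 ± 0.46 (SD, n = 3). Over the 8 probe sets the log2 difference ranged from -0.29 to 0.13 without IgM and from -0.30 to 0.32 with it, and the smallest limma adjusted p values (Benjamini-Hochberg) were 1 and 0.662. At an unadjusted p under 0.05, 0 of the 8 differed. Where these probe sets lie relative to the deleted part of the gene was not known here, and a probe set outside that part does not check the genotype labels.

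The first comparison asked how the genotype altered resting B cells. Several genes with values near the array floor in control cells were well above it in deleted cells. The retrotransposon-derived gene Rtl5 rose from 2.96 ± 0.22 to 10.67 ± 0.88 (SD, n = 3), a log2 change of 7.71 ± 0.71 (SE, n = 3 per group). The phospholipase Plb1 rose by 6.67 ± 0.43 and the glutaminyl cyclase Qpct by 6.26 ± 0.30. Hsd17b13, a lipid droplet protein, rose by 5.79 ± 0.23 (SE, n = 3 per group each). The other leading rises were Pla1a (5.69), the actin-bundling protein Pls1 (5.44), the transcription factor Zfhx3 (5.36), Fam241b (5.13), the protease inhibitor Slpi (4.99) and Tktl1 (4.89). Control means of 8 of these 10 genes lay under 4, near the floor, where the size and order of a rise are not exact. The methionine sulfoxide reductase Msrb3 fell by 3.36 (SE 0.58), and Serpinb7 fell by 3.001, Crisp3 by 2.97 and Grasp by 2.97. The cytokine gene Il1b fell by 2.91, the phosphatase Dusp14 by 2.75, Cyp4f18 by 2.70, the inhibitory receptor Ctla4 by 2.38, the tight junction gene Cldn10 by 2.28 and the immediate early gene Nr4a2 by 2.27. Adjusted p of these 20 genes from limma (Benjamini-Hochberg) lay between 5.42e-07 and 0.0149.

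In all, limma called 265 of 9293 genes (Benjamini-Hochberg adjusted p under 0.05), 189 higher and 76 lower in deleted cells. In each of the 265 the 3 arrays of one genotype lay beyond all 3 of the other, which held for 18.9% of all tested genes, against 10% by chance if the arrays are not paired. With the replicate number as a block the count was 640 (419 higher, 221 lower), which included all 265, and without deleted IgM replicate 3 it was 551, again with all 265. It was 133 and 162 without deleted unstimulated replicate 1 or 2, 146, 167 and 146 without control unstimulated replicate 1, 2 or 3, and 51 and 30 without all arrays of replicate 1 or 2.

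Some genes induced by antigen receptor signalling fell in resting deleted cells and others rose. Of 25 measured genes of the B cell receptor early response list, 6 fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone. Nr4a2 fell by 2.27, Dusp4 by 2.08 and Nr4a3 by 1.87, whereas the signalling inhibitor Spry2 rose by 2.63 ± 0.47 (SE, n = 3 per group). The list shifted down in limma's camera (adjusted p = 6.44e-10; adjusted p = 0.115 with an estimated correlation). In the overlapping list of NFAT targets and negative feedback genes, Nr4a1 fell by 1.77, while Spry1 rose by 3.63 and Spry2 by 2.63. It had 2 of 19 members higher and 3 lower, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0285, down; adjusted p = 0.442 with an estimated correlation). In the ribosome biogenesis list 1 of 26 genes fell, Nop58 by 1.19, and 1 adjusted over the list alone (camera adjusted p = 6.88e-06, down; adjusted p = 0.178 with an estimated correlation). In the list of amino acid transport and ATF4 targets 1 of 20 fell, Trib3 by 0.99, and 1 adjusted over the list alone (camera adjusted p = 0.000154, down; adjusted p = 0.115 with an estimated correlation). With the replicate block, 11 early response genes, 5 NFAT and feedback genes, 3 ribosome biogenesis genes and 2 amino acid genes fell. The NFAT and feedback list did not pass without deleted IgM replicate 3 (camera adjusted p = 0.0698).

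Further lists shifted down with no member past the threshold over all genes. For the 19 NF-kB targets camera gave an adjusted p of 0.000154 (adjusted p = 0.115 with an estimated correlation), and 1 fell adjusted over the list alone; Rel had a log2 difference of -1.26 and Ccl4 of -1.96 (limma adjusted p = 0.0544 and 0.172, or 0.00352 and 0.0455 with the replicate block). The 19 interferon-induced genes had an adjusted p of 0.0432 in camera (adjusted p = 0.492 with an estimated correlation), with 0 changed adjusted over the list alone. The 14 marginal zone B cell genes had an adjusted p of 0.0117 in camera (adjusted p = 0.115 with an estimated correlation), with 1 fall adjusted over the list alone. Among members, 6 NF-kB targets fell and 1 rose with the replicate block, and 2 interferon-induced genes and 1 marginal zone gene fell. The interferon-induced list did not pass without deleted IgM replicate 3 (camera adjusted p = 0.114). The 12 anti-apoptotic genes passed in camera with the replicate block (adjusted p = 0.0342) and not without it (adjusted p = 0.078; adjusted p = 0.442 with an estimated correlation).

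Among genes of cell survival, Bcl2l1, which encodes the anti-apoptotic protein Bcl-xL, averaged 8.50 ± 0.30 (SD, n = 3) in control and 7.34 ± 0.53 (SD, n = 3) in deleted cells. Its log2 difference of -1.16 ± 0.41 (SE, n = 3 per group) did not pass in limma (Benjamini-Hochberg adjusted p = 0.237), but did with the replicate block (adjusted p = 0.0033, with a range over all alternatives of 0.000487 to 1). When every probe set was tested, the other 2 probe sets of Bcl2l1 passed, with log2 differences of -1.93 (limma adjusted p = 0.0225) and -1.94 (limma adjusted p = 0.0118). The pro-apoptotic gene Bcl2l11, encoding Bim, fell by 0.92 (SE 0.20, limma adjusted p = 0.0323). Differences in Bcl2, -0.38, and Mcl1, 0.09, did not pass (limma adjusted p = 0.677 and 1).

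Some mitotic and immature B cell genes rose in deleted cells. In the G2/M and mitosis list 1 of 19 genes rose, the cyclin gene Ccna2 by 1.73 ± 0.38 (SE, n = 3 per group), and 8 rose adjusted over the list alone. Its median log2 difference was 1.33 (camera adjusted p = 6.44e-10; adjusted p = 0.115 with an estimated correlation). Of 13 immature and transitional B cell genes 4 rose and 1 fell, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000651; adjusted p = 0.178 with an estimated correlation). Dntt, which encodes terminal transferase of early lymphocytes, rose from 2.35 ± 0.07 to 5.73 ± 0.52 (SD, n = 3), the recombinase gene Rag1 rose by 1.71, Sox4 by 1.20 and Lef1 by 1.16. The replicate block gave 5 rises among the G2/M and mitosis genes.

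A few markers of other blood cells also passed the threshold. Measured were 9 of 19 listed macrophage and monocyte, 10 of 14 neutrophil and granule, 10 of 13 NK cell, 7 of 20 T cell and 5 of 14 erythroid markers. The filter took a value above 4 on any 3 arrays, so a marker near the floor in control cells could pass through deleted arrays. The macrophage and monocyte receptor gene Csf1r rose by 3.69 ± 0.72 (SE, n = 3 per group), whereas Adgre1, encoding the macrophage protein F4/80, fell by 1.45 (SE 0.31). That list had 1 rise and 1 fall among 9 genes, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00248, up; adjusted p = 0.42 with an estimated correlation). Of 10 neutrophil and granule markers none passed over all genes and 1 rose adjusted over the list alone, although the list shifted up in camera (adjusted p = 0.000154; adjusted p = 0.42 with an estimated correlation). The myeloperoxidase gene Mpo had a log2 difference of 3.20 ± 0.77 (SE, n = 3 per group; limma adjusted p = 0.0544, or 0.00265 with the replicate block). Of 10 NK cell markers Klrk1 rose, by 1.56, and 1 rose adjusted over the list alone (camera adjusted p = 0.00103, up; adjusted p = 0.442 with an estimated correlation). The 7 T cell markers (camera adjusted p = 0.0203, up; adjusted p = 0.442 with an estimated correlation) and the 5 erythroid markers (camera adjusted p = 0.000651, up; adjusted p = 0.227 with an estimated correlation) had 0 members past the threshold over all genes and 2 and 1 rises adjusted over the list alone. In the fit with the replicate block 5 macrophage and monocyte, 3 neutrophil and granule, 2 NK cell, 1 T cell and 1 erythroid markers rose. The T cell list did not pass without deleted IgM replicate 3 (camera adjusted p = 0.0563). The pan-B list did not pass (camera adjusted p = 0.0985), nor did the dendritic cell list (camera adjusted p = 0.409).

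**Figure D2:**
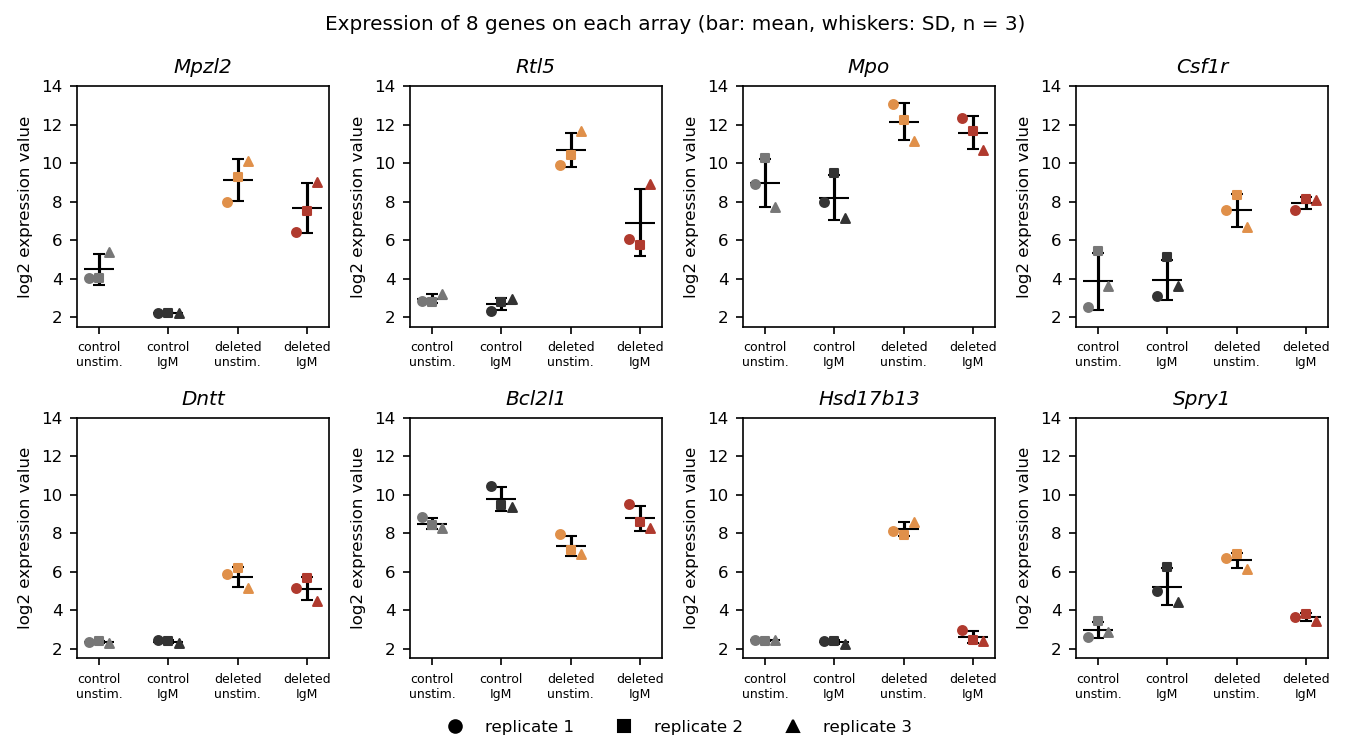
Log2 expression values of 8 genes on each of the 12 arrays, with the mean (bar) and SD (whiskers) of 3 arrays per group and symbols for the replicate number. Rtl5 averaged 2.96 in unstimulated control and 10.67 in unstimulated deleted cells, and Hsd17b13 averaged 8.21 in unstimulated deleted cells and 2.60 or less in the other 3 groups.

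The second comparison asked how the genotypes differed after 4 h with IgM. The adhesion protein gene Mpzl2 rose from the array floor of 2.23 in control cells to 7.66 ± 1.29 (SD, n = 3) in deleted cells, a log2 difference of 5.42 ± 0.67 (SE, n = 3 per group). Plb1 rose by 4.50, Rtl5 by 4.22, Ifit1bl1 by 4.08, Csf1r by 3.99 and the coagulation factor gene F13a1 by 3.95. The endothelial and leukocyte adhesion gene Pecam1 rose by 3.94 ± 0.46 (SE, n = 3 per group), Pls1 by 3.85, Cd34 by 3.64 and the DNA repair gene Neil1 by 3.37. Control means of 6 of these 10 genes lay under 4, near the floor, so the sizes and order of their rises are not exact. Pmp22 and Dusp14 each fell by 2.53, Crisp3 by 2.37, Ctla4 by 2.16 and the anti-inflammatory cytokine gene Il10 by 2.01. Smaller falls were those of Igf2bp3 (-1.91), Cdk5r1 (-1.77), Bdkrb1 (-1.76), Rbm47 (-1.66) and Dusp22 (-1.55). Adjusted p of these 20 genes from limma (Benjamini-Hochberg) lay between 0.000324 and 0.0499, and that of Il10 was 0.0888 without deleted IgM replicate 3 (range over all alternatives 0.00447 to 0.414).

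Here limma called 160 genes (Benjamini-Hochberg adjusted p under 0.05), 148 higher and 12 lower in deleted cells. All 160 had non-overlapping genotypes, which held for 17.9% of all tested genes, against 10% by chance for unpaired arrays. The replicate block gave 628 genes, including all 160, whereas a fit to only the 6 IgM arrays gave 0. The fit to all 12 arrays gave 98 genes when no filter was applied. The count was 60, 81 and 46 without control IgM replicate 1, 2 or 3, 3 and 0 without all arrays of replicate 1 or 2, and 218, of which 135 were shared, without deleted IgM replicate 3. Across genes, which are not independent replicates, the log2 difference correlated with genomic span at a Spearman rho of 0.39, against 0.03 without IgM.

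Some immature B cell genes rose with IgM as well. Of 13 genes in that list 5 rose, and 7 rose and 2 fell adjusted over the list alone, with Dntt up by 2.74, Rag1 by 2.37, Cd93 by 1.52 and Sox4 by 1.43 (camera adjusted p = 0.00216; adjusted p = 0.32 with an estimated correlation). In the G2/M and mitosis list Nusap1 rose, by 1.68, and 9 of 19 rose adjusted over the list alone (camera adjusted p = 4.79e-06; adjusted p = 0.32 with an estimated correlation). Of 22 FOXO targets and quiescence genes 3 rose, and 4 adjusted over the list alone, namely Rag1 by 2.37, the lymphocyte egress receptor gene S1pr1 by 1.41 and Ccng2 by 0.97 among those past the threshold over all genes (camera adjusted p = 0.0284; adjusted p = 0.314 with an estimated correlation). The macrophage and monocyte list had 2 rises among 9 genes, Csf1r and the adhesion molecule Vcam1 (2.74), and 3 adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.642 with an estimated correlation). The neutrophil and granule list had 0 rises over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0131, up; adjusted p = 0.675 with an estimated correlation). With the replicate block 8 G2/M, 5 macrophage and monocyte and 3 neutrophil and granule genes rose, and 1 immature B cell gene fell. The NK cell list passed with the replicate block (camera adjusted p = 0.0485) and not without it (camera adjusted p = 0.131; adjusted p = 0.815 with an estimated correlation).

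Other lists shifted down without a member past the threshold over all genes. The B cell receptor early response list had 7 of 25 falls adjusted over the list alone (camera adjusted p = 4.79e-06; adjusted p = 0.32 with an estimated correlation), and Fos had a log2 difference of -1.08 and Nr4a2 of -1.48 (limma adjusted p = 0.0702 and 0.0789, or 0.00482 and 0.0174 with the replicate block). The NF-kB targets had 2 of 19 falls adjusted over the list alone (camera adjusted p = 0.00744; adjusted p = 0.314 with an estimated correlation), with differences of -2.65 for the chemokine gene Ccl3 and -2.39 for Ccl4 (limma adjusted p = 0.0729 and 0.0883, or 0.0326 and 0.0232 with the replicate block). The ribosome biogenesis list (camera adjusted p = 0.0117; adjusted p = 0.642 with an estimated correlation) and the cholesterol synthesis and uptake list (camera adjusted p = 0.0279; adjusted p = 0.675 with an estimated correlation) had 0 changed adjusted over the list alone. In these lists 5 early response genes and 3 NF-kB targets fell with the replicate block. Bcl2l1 differed by -0.99 ± 0.41 (SE, n = 3 per group), which passed with the replicate block (limma adjusted p = 0.0103) and not without it (limma adjusted p = 0.307), with a range over all alternatives of 0.00628 to 0.742. Bcl2l11 differed by -0.05, Bcl2 by 0.29 and Mcl1 by 0.16, with limma adjusted p of 0.906, 0.527 and 0.723.

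The genotype effects without and with IgM came from different arrays and resembled each other. Of the genes higher in deleted cells, 80 were called in both settings, against 3.01 for independent lists, and of the lower genes 5, against 0.1. Across genes the log2 differences correlated with r = 0.592, where genes are not independent replicates, and 252 of the 265 genes called without IgM had the same sign with it. Unstimulated and IgM arrays of one replicate number deviated from their groups together, so the settings cannot be taken as independent cell preparations.

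**Figure D3:**
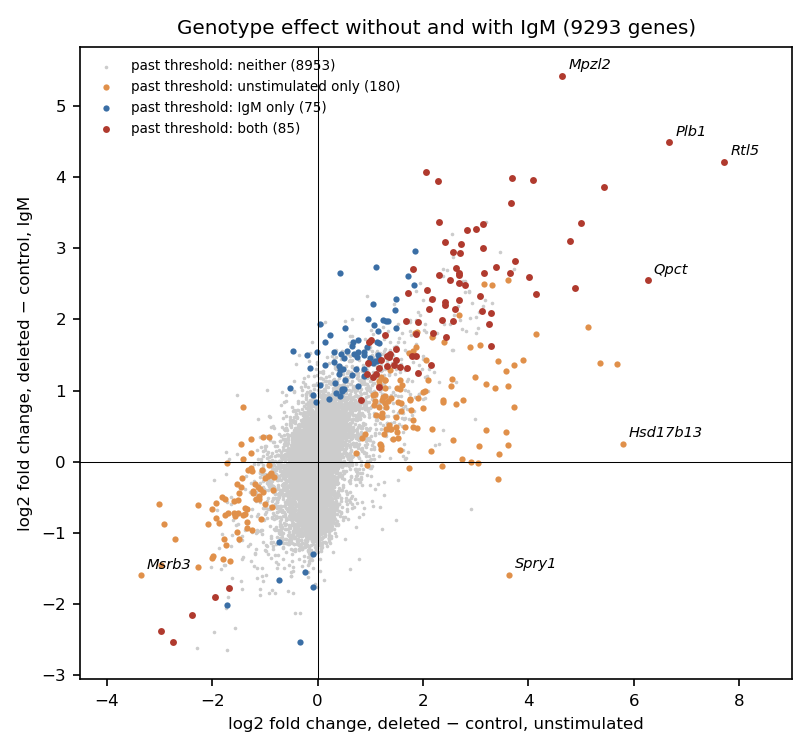
Log2 fold change between deleted and control cells without IgM (horizontal axis) and with IgM (vertical axis) for 9293 genes, with colours for genes past the threshold in neither, one or both settings. Mpzl2, Plb1 and Rtl5 were higher in both, Hsd17b13 rose by 5.79 only on the horizontal axis, and Spry1 lay at 3.63 and -1.59.

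The third comparison asked what IgM did in control cells. The interleukin receptor gene Il1r1 rose from 3.01 ± 0.26 to 7.50 ± 0.50 (SD, n = 3), a log2 change of 4.49 ± 0.32 (SE, n = 3 per group). Lonrf3 rose by 4.26, Rragd, an activator of the nutrient sensor mTORC1, by 3.97, the receptor kinase gene Axl by 3.94 and the transcription factor gene Maff by 3.79. Lipg rose by 3.56, Plcxd1 by 3.54, Bex1 by 3.50, the sphingosine phosphate receptor gene S1pr3 by 3.49 and the repressor gene Gfi1 by 3.45, and 4 of these 10 started from means under 4. The glycosyltransferase gene B3gnt8 fell by 4.65 ± 0.51 (SE, n = 3 per group), Rasgrp2 by 4.52, Hepacam2 by 4.28, the kinase gene Lrrk2 by 4.28, Cyp4f18 by 4.14 and Arhgef18 by 4.04. Ifit1bl1 fell by 4.01, Il10ra by 3.94, Pecam1 by 3.94 and Klhl14 by 3.93. Adjusted p of these 20 genes from limma (Benjamini-Hochberg) lay between 3.32e-05 and 0.0396.

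IgM changed 1920 genes in control cells by limma (Benjamini-Hochberg adjusted p under 0.05), 809 up and 1111 down, and in 1917 of them the 3 arrays of each condition did not overlap, as for 45.5% of all tested genes, against 10% by chance for unpaired arrays. The excess of falls depended on scaling, since centring each array on its median gave 951 up and 948 down. With the replicate block the count was 3299, and without deleted IgM replicate 3, which enters here only through the shared spread, it was 3356; each included all 1920. The count was 1235 without control IgM replicate 3 and 544 and 290 without all arrays of replicate 1 or 2.

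The lists that shifted up in camera held early response, ribosome biogenesis and metabolic genes, among others. In the B cell receptor early response list 14 of 25 genes rose, and 16 rose and 1 fell adjusted over the list alone, with Maff up by 3.79, Rgs1 by 3.42, Nr4a2 by 3.28 and Egr2 by 2.79 (camera adjusted p = 5.28e-10; adjusted p = 0.119 with an estimated correlation). Of 26 ribosome biogenesis genes 19 rose, and 24 adjusted over the list alone, among them the polymerase subunit gene Polr1b by 1.89 and Rrp12 by 1.79 (camera adjusted p = 4.01e-12; adjusted p = 0.0497 with an estimated correlation). Of 20 amino acid transport and ATF4 targets 13 rose and 1 fell, or 16 and 1 adjusted over the list alone. Atf5 and the transporter gene Slc1a4 each rose by 1.67, and Slc43a2 fell by 2.32 (camera adjusted p = 7.46e-07; adjusted p = 0.0446 with an estimated correlation). Of 16 cholesterol synthesis and uptake genes 9 rose, and 9 adjusted over the list alone, including Lss by 2.01 and Idi1 by 1.78 (camera adjusted p = 7.66e-07; adjusted p = 0.27 with an estimated correlation). In the glycolysis list 6 of 14 rose, and 6 rose and 1 fell adjusted over the list alone, including the hexokinase gene Hk2 by 1.98 (camera adjusted p = 0.0201; adjusted p = 0.36 with an estimated correlation). Of 19 NF-kB targets 6 rose and 1 fell, or 9 and 2 adjusted over the list alone, with Tnf at 1.47, Rel at 1.28 and Bcl3 at -1.91 (camera adjusted p = 0.0209; adjusted p = 0.167 with an estimated correlation). Activation surface proteins had 7 rises and 1 fall among 14, or 8 and 1 adjusted over the list alone, including Il2ra (1.78) and the early activation marker gene Cd69 (1.52), against -3.82 for Icosl (camera adjusted p = 0.0178; adjusted p = 0.286 with an estimated correlation). In the dendritic cell list 3 of 8 genes rose, and 3 adjusted over the list alone, namely Zbtb46 (1.51), Klk1 (1.499) and Ccr9 (1.30) (camera adjusted p = 0.0451; adjusted p = 0.286 with an estimated correlation); other probe sets of Klk1 had log2 changes of -0.71 and -0.49. The dendritic cell list did not pass without deleted IgM replicate 3 (camera adjusted p = 0.053). Of the NF-kB targets 10 rose and 3 fell with the replicate block, and 1 early response and 1 glycolysis gene fell.

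Another 6 lists shifted down in camera, of which 2 held with an estimated correlation. Of 22 FOXO targets and quiescence genes 11 fell and 2 rose, or 13 and 2 adjusted over the list alone. The cell cycle inhibitor gene Cdkn2d fell by 2.65 and Klf2 by 2.55, and Irs2 rose by 2.25 (camera adjusted p = 0.00122; adjusted p = 0.0446 with an estimated correlation). Of 20 pan-B cell genes 8 fell and 1 rose, or 13 and 1 adjusted over the list alone, including Bank1 (-2.60), Cd22 (-2.01) and the lineage factor gene Pax5 (-1.77) (camera adjusted p = 0.000156; adjusted p = 0.0446 with an estimated correlation). Of 19 B cell receptor signalling components 8 fell, and 12 fell and 1 rose adjusted over the list alone, with the kinase gene Syk down (-2.95) (camera adjusted p = 0.000931; adjusted p = 0.167 with an estimated correlation). Of 19 interferon-induced genes 5 fell, and 7 adjusted over the list alone, including Ifit3 (-3.42) and Ifit2 (-2.78) (camera adjusted p = 0.000931; adjusted p = 0.36 with an estimated correlation). Of 12 antigen presentation genes 5 fell, and 6 adjusted over the list alone, including H2-Oa (-2.28) and H2-DMa (-2.06) (camera adjusted p = 0.0104; adjusted p = 0.413 with an estimated correlation). In the follicular list 4 of 10 fell and 1 rose, or 4 and 2 adjusted over the list alone, with Cd55 at -3.58 (camera adjusted p = 0.0451; adjusted p = 0.167 with an estimated correlation, adjusted p = 0.092 with the replicate block and 0.0737 without deleted IgM replicate 3). With the replicate block 15 pan-B genes, 13 receptor signalling components and 9 interferon-induced genes fell, and 2 receptor signalling and 2 follicular genes rose. Bcl2l1 rose by 1.27 ± 0.41 (SE, n = 3 per group; limma adjusted p = 0.0481), Bcl2 fell by 1.73, and Bcl2l11 (0.37) and Mcl1 (-0.27) did not pass (limma adjusted p = 0.23 and 0.441).

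The fourth comparison asked the same of deleted cells. Lonrf3 rose by 4.64 ± 0.30 (SE, n = 3 per group), Amz1 by 4.61, S1pr3 by 4.42, Axl by 4.28, Tacc2 by 4.26 and Plcxd1 by 4.11. The immediate early genes Nr4a2 and Egr2 rose by 4.06 and 3.86, Grasp by 4.00 and Hivep3 by 3.81, and 3 of these 10 started from means under 4. Hsd17b13 fell by 5.61 ± 0.23 (SE, n = 3 per group), from 8.21 ± 0.36 to 2.60 ± 0.31 (SD, n = 3). B3gnt8 fell by 4.51, Zfhx3 by 4.07, Pla1a by 3.97, the calcium-binding protein gene S100a6 by 3.91, Rtl5 by 3.76, Qpct by 3.71, Acp5 by 3.69, Rasgrp2 by 3.62 and Vangl2 by 3.61. Adjusted p of these 20 genes from limma (Benjamini-Hochberg) lay between 7.53e-07 and 0.0343, and that of Hivep3 was 0.0607 without deleted IgM replicate 3 (range over all alternatives 0.000171 to 0.175).

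In deleted cells 1765 genes changed by limma (Benjamini-Hochberg adjusted p under 0.05), 909 up and 856 down, and 1751 of them had non-overlapping conditions, as did 34.5% of all tested genes, against 10% by chance for unpaired arrays. The balance of directions depended on the fit, with 1612 up and 1796 down with the replicate block, and 998 up and 717 down with each array centred on its median. The total was 3408 with the replicate block, including all 1765, and 540 in a fit to only the 6 deleted arrays. It was 1021 and 1176 without deleted unstimulated replicate 1 or 3, and 388 and 190 without all arrays of replicate 1 or 2. Across genes the log2 change correlated with genomic span at a Spearman rho of 0.20, against -0.04 in control cells.

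The early response, ribosome biogenesis and metabolic lists shifted up in camera in deleted cells, and 0 of the 9 lists called in this comparison held with an estimated correlation. The B cell receptor early response list had 14 rises among 25 genes, and 16 rises and 1 fall adjusted over the list alone, including Nr4a3 by 3.34 (camera adjusted p = 6.15e-10; adjusted p = 0.152 with an estimated correlation). Of 26 ribosome biogenesis genes 21 rose, and 24 adjusted over the list alone, including Polr1b by 2.65 and Nolc1 by 2.46 (camera adjusted p = 1.78e-13; adjusted p = 0.0746 with an estimated correlation). Of 20 amino acid transport and ATF4 targets 14 rose and 1 fell, and as many adjusted over the list alone, with Slc1a4 up by 2.48 and Trib3 by 1.98 (camera adjusted p = 5.06e-08; adjusted p = 0.0746 with an estimated correlation). Of 16 cholesterol genes 8 rose, and 9 adjusted over the list alone, including Idi1 by 1.998 and Cyp51 by 1.96 (camera adjusted p = 9.07e-05; adjusted p = 0.425 with an estimated correlation). In the glycolysis list 6 of 14 rose and 1 fell, or 7 and 1 adjusted over the list alone, with the lactate transporter gene Slc16a1 at 2.55 and Hk1 at -1.57 (camera adjusted p = 0.0151; adjusted p = 0.425 with an estimated correlation). Of 19 NF-kB targets 6 rose and 1 fell, and as many adjusted over the list alone, with Rel at 2.24 and Bcl3 at -1.66 (camera adjusted p = 0.0299; adjusted p = 0.277 with an estimated correlation).

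The FOXO, interferon-induced and receptor signalling lists shifted down in camera in deleted cells. Of 22 FOXO targets and quiescence genes 7 fell and 1 rose, or 8 and 1 adjusted over the list alone, with Cdkn2d at -3.32 and Klf2 at -2.68 (camera adjusted p = 0.0287; adjusted p = 0.152 with an estimated correlation). Of 19 interferon-induced genes 5 fell, and 5 adjusted over the list alone, including Ifit3 (-2.26) (camera adjusted p = 0.0287; adjusted p = 0.629 with an estimated correlation). This list did not pass without deleted IgM replicate 3 (camera adjusted p = 0.0717). Of 19 B cell receptor signalling components 5 fell and 2 rose, or 10 and 3 adjusted over the list alone, with Syk at -2.06 and Pik3ap1 at 1.69 (camera adjusted p = 0.0287; adjusted p = 0.425 with an estimated correlation). With the replicate block 11 FOXO and quiescence genes fell and 2 rose, and 10 interferon-induced genes, 12 receptor signalling components and 1 early response gene fell. The pan-B list passed with the replicate block (camera adjusted p = 0.0422) and not without it (camera adjusted p = 0.0868; adjusted p = 0.369 with an estimated correlation). Bcl2l1 rose by 1.44 ± 0.41 (SE, n = 3 per group; limma adjusted p = 0.0311) and Bcl2l11 by 1.25 (limma adjusted p = 0.00177), Bcl2 fell by 1.06 (limma adjusted p = 0.00582), and Mcl1 differed by -0.21 (limma adjusted p = 0.527).

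**Figure D4:**
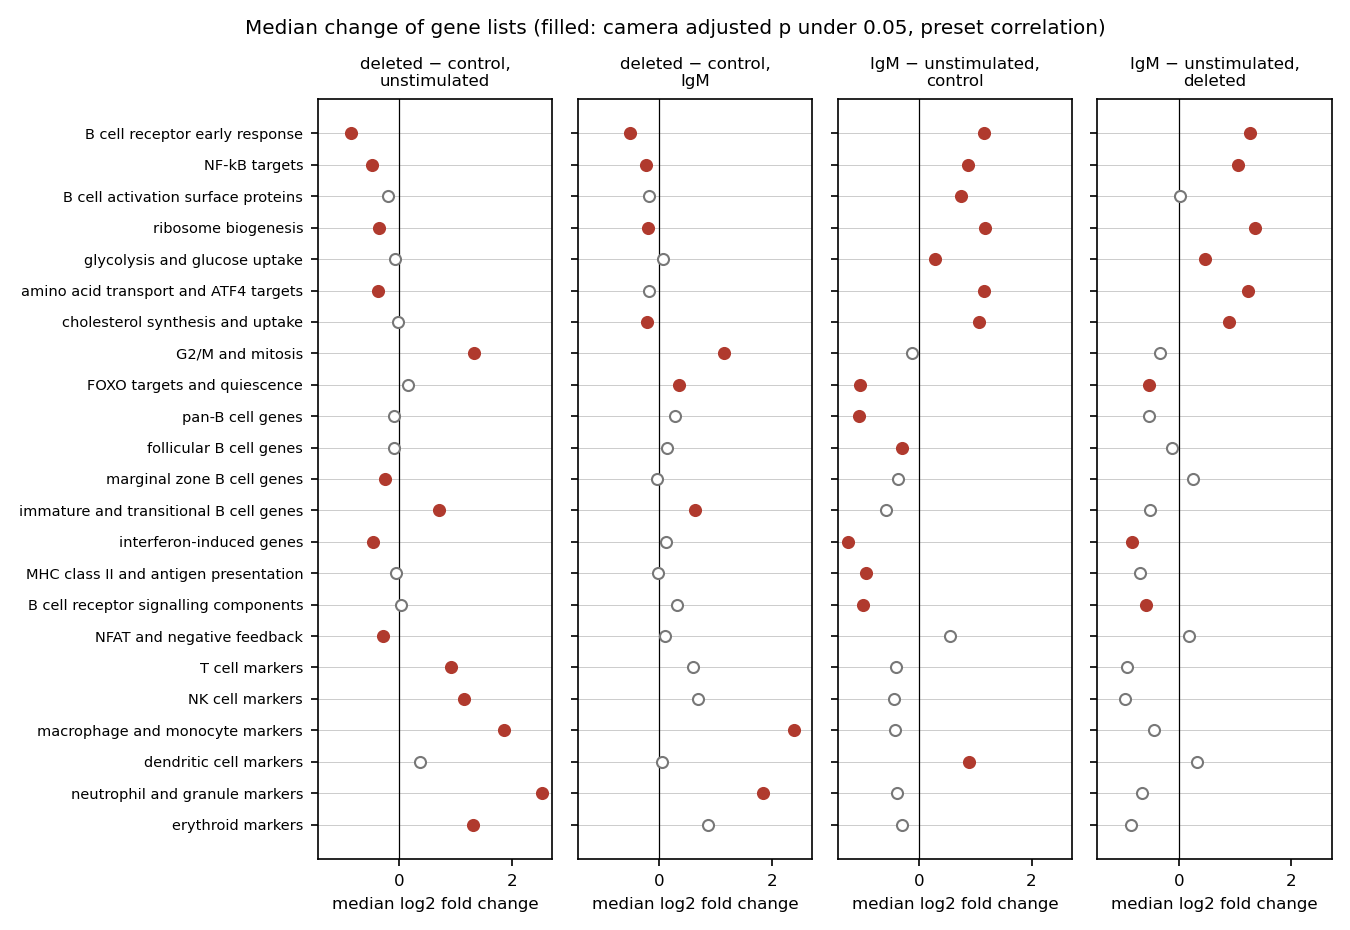
Median log2 fold change of the gene lists that passed camera in at least 1 of the 4 comparisons, on one common axis, with filled points where the camera adjusted p was under 0.05 at the preset correlation. The median of the ribosome biogenesis list was 1.17 in control and 1.36 in deleted cells after IgM, and that of the neutrophil and granule list was 2.53 between genotypes without IgM, with medians of 4.74, 0.87 and 1.53 for replicate numbers 1, 2 and 3.

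The responses of both genotypes to IgM were alike in direction. Of the genes that rose, 645 were called in both genotypes, against 79.13 for independent lists, and of the genes that fell 623, against 102.34. The log2 changes correlated across genes with r = 0.807, and 1902 of the 1920 genes called in control cells had the same sign in deleted cells.

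The interaction asked which responses to IgM differed between genotypes. It held 10 genes by limma (Benjamini-Hochberg adjusted p under 0.05), all with a negative value, meaning a genotype difference that was lower with IgM than without. In 8 of the 10, control cells had means under 4, near the array floor, without and with IgM, so a fall with IgM could not have been seen in control cells. An unadjusted p under 0.05 was reached by 355 genes, fewer than the 465 that no change would give. Differences between replicate numbers remained in the spread of this fit, so the low number does not show that no response differed. Across genes the interaction correlated with genomic span at a Spearman rho of 0.39. Hsd17b13 had a value of -5.53 ± 0.32 (SE; limma adjusted p = 3.38e-05). Spry1, an inhibitor of receptor signalling, followed with -5.22 ± 0.60 (SE; limma adjusted p = 0.00597): in control cells its mean was 2.97 without and 5.22 with IgM, in deleted cells 6.60 and 3.64. Zfhx3 (-3.97), Qpct (-3.71), Neo1 (-3.38), Il1r1 (-2.95), Tmtc1 (-2.83), the growth factor gene Tgfa (-2.74) and the sodium channel gene Scn11a (-2.70) were the others named by the rule. Il1r1 stood at 3.01 in control and 6.74 in deleted cells without IgM, and at 7.50 and 8.28 with it. Lists with an upward interaction were the pan-B genes (camera adjusted p = 0.00731; adjusted p = 0.202 with an estimated correlation), the migration and adhesion receptors (camera adjusted p = 0.00731; adjusted p = 0.236 with an estimated correlation) and the marginal zone genes (camera adjusted p = 0.0269; adjusted p = 0.202 with an estimated correlation), with 0 members past the threshold over all genes and 0, 0 and 1 adjusted over the list alone. Their median interactions of 0.53, 0.51 and 0.83 were 0.35, 0.52 and 0.54 without deleted IgM replicate 3. In camera 0 of these 3 lists passed without all arrays of replicate 1, and all 3 passed without those of replicate 2 or 3. The interactions of Bcl2l1 (0.17), Bcl2l11 (0.87), Bcl2 (0.67) and Mcl1 (0.06) did not pass (limma adjusted p of 0.824 to 0.966). The replicate block gave 16 genes (2 higher, 14 lower), including all 10, and the count was 16, 9 of them shared, without deleted IgM replicate 3, where Zfhx3 no longer passed (limma adjusted p = 0.0529, range over all alternatives 0.0039 to 0.977). It was 6 without deleted IgM replicate 2, without any single control IgM array, or without control unstimulated replicate 2 or 3, and 1 and 0 without all arrays of replicate 1 or 2.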

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

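Some tests in this part were chosen after the results they address were seen. They were those of the poly-A controls, the share of B cells (with its pairs of marker lists), mature neutrophils and chromosome 6. The tests of a wrong array label and of progenitor genes also address patterns seen in the data, so they were chosen later too. The progenitor genes were not among the 35 lists.

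The interaction test singled out 10 genes and 3 lists. For 8 of the 10 genes both control means lay under 4, near the array floor, where a fall with IgM cannot be seen, so for these the test does not show that the genotypes responded differently. The interactions (log2) were -5.53 for Hsd17b13, -5.22 for Spry1, -3.97 for Zfhx3, -3.71 for Qpct, -3.38 for Neo1, -2.95 for Il1r1, -2.92 for Gm19935, -2.83 for Tmtc1, -2.74 for Tgfa and -2.70 for Scn11a, with limma adjusted p of 3.38e-05 to 0.0439. The median interactions of the lists were 0.53 for pan-B cell genes, 0.83 for marginal zone B cell genes and 0.51 for migration and adhesion receptors, or 0.35, 0.54 and 0.52 without deleted IgM replicate 3 (camera adjusted p = 0.00731, 0.0269 and 0.00731; adjusted p = 0.202, 0.202 and 0.236 with an estimated correlation). Among 100 drawn regroupings of genotype within each stimulation, the real one included, 5 gave 10 or more genes, with 33 as the highest other, and the highest among the 15 others that parted all same-numbered pairs in both stimulations was 18. The 4 others that gave as many all kept the real genotype split of the unstimulated arrays, and so carried the real genotype effect into the interaction. The 91 that mixed the unstimulated genotypes gave 2 or fewer. The share of regroupings therefore does not decide whether chance can be excluded.

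For the other 4 comparisons, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many genes. The real counts were 265, 160, 1920 and 1765, and the highest other count was 0 in each comparison, which includes the 3 other splits that parted all same-numbered pairs, with or without the replicate block. With 10 splits the share cannot fall under 0.1. Each other split mixes the real groups, so real differences add to its spread, and its count of 0 does not measure false calls.

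Deleted IgM replicate 3 stood apart from the other 2 arrays of its group. A wrong genotype or stimulation label was argued against. Of the genes called without the array, 77.5% of 551 genotype genes and 78.87% of 3356 IgM genes kept their direction on it. These shares lay above the 75% written in advance of the test, though after the array was seen to stand apart. The margin is thin, genes are not independent, and the shares on the other 2 arrays were 92.6% or more. A loss of short transcripts in labelling or amplification stays open as a candidate explanation: the poly-A control level lay 1.11 log2 units below the lowest of the other 11 arrays (a gap of -1.11, against an SD of 0.39 among the other 3 arrays of replicate 3). A weaker dependence on genomic span was also present between replicates 3 and 1 of the other groups. Their median differences ran from -0.36 in the shortest genes to 0.19 in the longest, and correlated with those of this array across genes (r = 0.68). Genomic span is not transcript length, which was not measured. No biological explanation was tested.

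Lists of macrophage, granule, NK, T and erythroid markers shifted up in unstimulated deleted cells at the preset correlation and not with an estimated one, with 1 macrophage and 1 NK marker higher and 1 macrophage marker lower past the threshold, although sorting on B220 would remove most such cells. Only 9 of 19 listed macrophage, 7 of 20 T cell and 5 of 14 erythroid markers were measured, and the others did not enter these shifts. A smaller share of B cells cannot be told apart from other explanations. Its test presumed that markers of all other types would rise alike, which need not hold if only some types replaced B cells. The granule list exceeded the T cell list by 1.46 log2 units (SD 1.97 over the 3 replicate numbers). The macrophage list exceeded the dendritic list by 1.32 (SD 0.19). That excess was 0.37 (SD 0.40) among markers under 6 in control cells, where B cell signal hides less. Of 15 pairs of lists 3 moved apart in one direction by more than their SD, and 1 among the markers under 6. There the T cell list minus the macrophage list was -0.78 (SD 0.51). Unequal rises of this kind do not decide whether the share of B cells was smaller. Mature neutrophils stay open too, since Mpo, Elane and Prtn3 exceeded S100a8 and S100a9 by 0.46 (SD 1.56). Haematopoietic progenitor cells among the sorted deleted cells may contribute. The median change of 18 measured progenitor genes, 1.36, lay at percentile 100 of 10000 random lists matched on mean level. Camera gave an unadjusted p of 2.86e-11, or 0.0257 with an estimated correlation. These were not adjusted over lists, unlike the camera values of the 33 lists, and cannot be set beside them. Genes of a random list need not vary together, and the T cell and granule lists also rose, with medians of 0.91 and 2.53. The percentile therefore cannot tell progenitor cells from other sources of such a rise. Of the 18, 3 passed the threshold: Cebpa (2.68), Ms4a2 (2.52) and Lmo2 (1.29). Ctsg, at 6.89 in control and 10.20 in deleted cells, did not pass (limma adjusted p = 0.122). Cdca7 (-0.65) and Zfpm1 (-0.32) were lower in deleted cells, without passing. That list also holds mast cell and basophil genes, and an effect of the genotype on gene expression in B cells stays open and untested.

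As the main source of the genotype effect in unstimulated cells, linked variants or regulatory changes that alter genes near Foxp1 were argued against. Chromosome 6, which carries Foxp1, held 5.28% of the changed genes (14 of 265), against 4.87% of all tested genes. Within 5, 10, 20 and 30 Mb of Foxp1, 1 of 10, 1 of 32, 4 of 134 and 4 of 228 genes had changed, against 0.29, 0.91, 3.82 and 6.5 by chance (Fisher's exact test, one-sided, p = 0.251, 0.604, 0.534 and 0.895, adjusted p = 0.805 to 0.895 over the 4). A linked change that alters genes elsewhere in the genome would not be seen in these counts and stays open. Unlinked differences in background between the mixed-strain mice were not tested.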

How the results depend on the processing

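Chosen after the data were seen were the fits without deleted IgM replicate 3 for the gene lists, those that join its removal to the replicate block, and those with the poly-A control level as a covariate, and array weights were estimated gene by gene after the default algorithm did not converge. Counts below are in the order deleted against control without IgM, the same with IgM, IgM in control cells, IgM in deleted cells, and interaction. The interaction genes were all lower in the reported fit, but 32 were higher and 48 lower with array weights, 6 and 23 with the random block, 8 and 27 with the poly-A covariate, and 107 and 80 with the block and no deleted IgM replicate 3 array. The reported counts of genes were 265, 160, 1920, 1765 and 10. They were 640, 628, 3299, 3408 and 16 with the replicate block, 643, 643, 3210, 3301 and 29 with the replicate number as a random block, and 847, 702, 3876, 3578 and 80 with array weights, where deleted IgM replicate 3 had a weight of 0.055. The replicate 2 arrays had weights of 2.706 to 3.415 and the remaining arrays 0.739 to 1.132, so the weighted counts rest largely on replicate 2. The counts were 747, 834, 3877, 3365 and 35 with the poly-A covariate, and 2007, 1223, 5874, 4976 and 187 with the block and no deleted IgM replicate 3 array. With every probe set past the filter, where more features are tested, IgM changed 3483 in control and 3260 in deleted cells, and the interaction held 19. Fits to only the arrays compared gave 301 for the genotypes without IgM and 2738 for IgM in control cells, both above the reported counts. They gave 0 for the genotypes with IgM and 540 for IgM in deleted cells. The comparisons whose counts fell are those that hold deleted IgM replicate 3. No filter gave 98 for the genotypes with IgM, and a filter at 6 gave 4 for the interaction; the cause was not tested. Leaving out arrays, singly or by replicate number, gave 30 to 551, 0 to 218, 290 to 3356, 190 to 2390 and 0 to 16 genes, with each lowest count without replicate 2 and each highest without deleted IgM replicate 3.

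Of 8679 alternative values of the 311 gene changes past the threshold, 7453 kept direction and call, 1225 kept direction only and 1 reversed: Klk1 after IgM in deleted cells was -0.326 with the mean of its probe sets (adjusted p = 0.641). All 311 passed with the replicate block. Foxp1 passed in 0 of 28 alternatives in either setting, with log2 differences of -0.344 to 0.277 without IgM and -0.336 to 0.217 with it. The lists that passed camera numbered 14, 9, 14, 9 and 3, and 0, 0, 4, 0 and 0 with an estimated correlation. The 4 that held were ribosome biogenesis, amino acid transport and ATF4 targets, FOXO targets and quiescence, and pan-B genes in control cells. Fry gave 7, 8, 17, 17 and 4, of which 6, 4, 14, 8 and 2 were among the reported calls, so many genotype list calls did not pass it. No filter gave 14 for IgM in deleted cells and 10 for the interaction, and a further quantile normalization gave 5 for the interaction. Leaving out all arrays of 1 replicate number gave 0 to 5 for the interaction, and the 0 was without replicate 1. Without deleted IgM replicate 3 there were 11, 14, 12, 9 and 10, and with the block as well 13, 14, 12, 9 and 13. Without the array alone, 11, 9, 12, 8 and 3 of them were among the reported calls, so some calls were gained. The lists lost without that array were interferon-induced, NFAT and T cell genes for the genotypes without IgM (adjusted p = 0.114, 0.0698 and 0.0563), dendritic and follicular genes for IgM in control cells (0.053 and 0.0737) and interferon-induced genes for IgM in deleted cells (0.0717). Counts of members moved as well, from 6 to 10 falls in the early response list between genotypes without IgM and from 8 to 14 in the pan-B list after IgM in control cells. Apart from the list calls given with their comparisons, the replicate block ended or added no list call. No list that passed turned its median under either other scaling, and the median of all genes moved by less than 0.1. Signal over background limits what can be seen: 58.9% to 59.9% of probe sets per array lay at or below 4.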
